A study of Mus musculus with 6 samples.

How the data were processed

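Total RNA from a brainstem and cerebellum dissection of 16-week-old mice was measured on single-colour (Cy3) Agilent mouse arrays, 1 array per sample. The labels give 3 wild-type and 3 MSA transgenic samples, and each sample's title carries a number of its own. The labels do not state that these numbers are separate animals, so p-values measure the spread between these samples. Per the file headers, the arrays were read with Feature Extraction 10.7.1.1 under protocol GE1_107_Sep09 and annotated on genome build mm9. Per the submitters' processing notes the version was 9.5.1.1, and the files' own version is used here. Spot values in the deposited files are intensity values on a linear scale, background-subtracted by the scanner software per the file headers, with flags per spot for signal above background, saturation and outliers. The authors also deposited a value table of intensity values. When set against the scanner files, at least 99.986% of each column's values equalled a quantile normalization of the probe-averaged signals on the linear scale within 0.01 log2. Each column's median was 59.9, on a linear scale and without centring. This table served only as an alternative.

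For every array the log2 of the processed signal was taken and the log2 of the array's 75th percentile subtracted. Control spots and 39 to 84 outlier-flagged spots per array were left out, no spot was saturated, and spots of one probe were averaged. Of 56605 probes, 32994 were named by accession through the RefSeq gene table given with the data (assembly GRCm38.p6, used for names only), 10224 by symbol and 520 by synonym. The other 12867 kept the name in the files. Probes well above background on all arrays of at least 1 genotype were tested (38463 probes). For each gene the tested probe with the highest mean level was kept, which left 24932 genes, 18104 of them with a reference name. Genotypes were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Where a gene is not well above background on any array of a genotype it would have only a bound. None of the called genes was in that position.

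Fixed before the data were examined were 31 gene lists for hindbrain cell types, pathways, other tissues, strain and sex. They were tested with camera (preset correlation 0.01, 2-sided, Benjamini-Hochberg over lists), with camera with an estimated correlation and with fry. The positions of the 200 genes with the smallest p were compared with those of all tested genes per chromosome by Fisher's exact test. Genes named in the text follow a rule fixed beforehand. It takes 10 genes whatever their values (some of the genes it takes are not reported here), up to 12 called genes in each direction with separated groups, up to 6 uncalled genes with the smallest p where fewer than 12 were called, and up to 4 members per list with the smallest p. Predicted genes are only counted, except in counts of 5 or fewer, and any other gene is stated to have been chosen after its values were seen.

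The steps were tested on simulated data with the real genes and spread. In the transgenic against wild-type comparison of 24932 genes, 47% of 100 genes planted at a log2 change of 1 and 78% of 100 planted at 2 were recovered, with 7 false calls. Each gene's estimated SD was taken as its true SD. The Benjamini-Hochberg cut is stricter where fewer genes pass, as on the real arrays with 11 calls, so these shares need not hold there. A shifted list and a planted chromosome were both found, with 0 calls among lists sharing no gene with the shifted one and among other chromosomes. The simulated genes varied independently, so this does not show how often camera calls lists falsely on the real arrays. The number of arrays limits the precision. Alternatives covered background correction, scaling, the filter on dim probes, the authors' value table, slide and the title number's first digit as blocks, the variance model, the probe chosen per gene, thresholds, the set test and leaving out each sample. That digit is 7 for replicate 1 of each genotype and 8 for the others. Background correction was normexp with an offset of 50 intensity units, where the arrays' median signals were 39.6 to 67.5. That offset by itself shrinks the log2 differences of dim genes. Replicate numbers here only name samples and were not used to pair any. The title numbers are 757, 809 and 811 for wild type and 756, 810 and 812 for transgenic samples. The labels do not say whether neighbouring numbers are related, and no paired fit was run. No reference genome was used here.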

Results

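RNA from a brainstem and cerebellum dissection was measured in 3 wild-type samples and 3 samples from mice labelled MSA transgenic, all aged 16 weeks. The labels neither spell out MSA nor name the transgene, and they give 1 mixed strain background for both genotypes and no sex. Each sample was hybridised to 1 single-colour mouse array. Wild-type replicate 1 was alone on slide 1, and the other 5 arrays shared slide 2. The 75th percentile of the deposited signal was 405.7 intensity units on wild-type replicate 1 and between 535.0 and 609.2 on the others. On that array 66.4% of probes lay well above background, against 70.0% to 72.9% on the rest. Its correlation with the other arrays across genes was 0.974 to 0.978, while the 5 arrays of slide 2 correlated at 0.991 to 0.996 with one another, so no sample was a copy of another. The extraction quality flag in the files was in range for wild-type replicate 1 and transgenic replicate 3, and evaluate for the other arrays.

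The series design asks how gene expression in transgenic brain differs from that in wild-type brain at this age. Genes of activated microglia and a few other genes rose in the transgenic samples, and an oligodendrocyte protease fell. Nmu, which encodes the neuropeptide neuromedin U, was 61.6-fold higher (log2 difference 5.94 ± 0.43, SE, n = 3 per genotype, as for all values below). Itgax, an integrin subunit of myeloid cells, rose 13.5-fold, the chemokine gene Ccl3 11.6-fold, Kdr, which encodes a receptor for vascular endothelial growth factor, 10.2-fold, and Clec7a, a pattern recognition receptor of phagocytes, 9.96-fold. With normexp background correction the log2 difference of Nmu was 4.14, that of Itgax 1.42, that of Ccl3 1.31 and that of Clec7a 2.31 in place of 3.32, all still called. Klk6, a secreted protease made in quantity by oligodendrocytes, was 4.18-fold lower (log2 difference -2.06 ± 0.12).

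**Figure D1:**
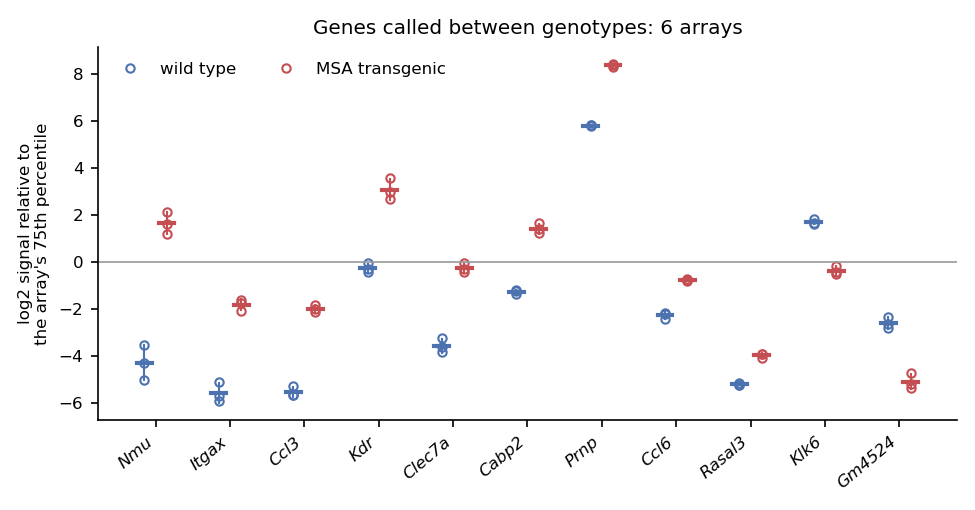
Signal of the genes called between genotypes, as log2 relative to each array's 75th percentile (vertical axis), with 1 open circle per array, thick bars at the means and thin bars for the SD of 3 wild-type (blue) and 3 MSA transgenic (red) arrays. For each gene the 3 transgenic values lie on one side of the 3 wild-type values, from Prnp with means of 5.81 and 8.38 to Nmu with means of -4.28 and 1.66.

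In limma with Benjamini-Hochberg adjustment over 24932 genes, 11 genes passed an adjusted p of 0.05, 9 higher and 2 lower in the transgenic samples. The smallest adjusted p, 0.00164, belonged to Prnp, the prion protein gene, which was 5.92-fold higher (log2 difference 2.56 ± 0.08). Cabp2, a calcium-binding protein gene, rose 6.48-fold, the chemokine gene Ccl6 2.83-fold and Rasal3, which encodes a Ras GTPase-activating protein of blood cells, 2.36-fold. The second lower gene, the predicted gene Gm4524, named after its values were seen, had a log2 difference of -2.50 ± 0.20. Itgax and Ccl3 were well above background on all 3 transgenic arrays but on only 1 of the 3 wild-type arrays, so their folds are set against signals close to background. With normexp background correction their log2 differences of 3.76 and 3.54 became 1.42 and 1.31, both still called. Itgax missed the threshold with quantile normalization (limma adjusted p = 0.0505) and with the authors' value table (0.0512). The log2 difference of Rasal3 fell from 1.24 to 0.21 with normexp, no longer called. The normexp offset of 50 units shrinks the log2 differences of dim genes by itself, so such drops do not tell whether a change is real. All 11 genes differed by at least 2-fold and had non-overlapping groups, a separation found in 14.9% of all genes where chance gives 10%.

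Several genes came close to the threshold without being called. Cd52, a surface glycoprotein of leukocytes, was at 3.20 times its wild-type level (limma adjusted p = 0.0565), Gpr65, a proton-sensing receptor, at 2.82 times (0.0522), Cd68, a lysosomal protein of phagocytes, at 2.14 times (0.0591) and Slc11a1, a metal transporter of phagosomes, at 2.11 times (0.0567). The transcription factor gene Egr2 was at 2.52 times (0.0522) and the interferon-induced gene Oas1a at 2.09 times (0.0542). With normexp the log2 differences were 0.38 for Gpr65, 0.57 for Slc11a1 and 0.33 for Egr2. In the other direction, Fa2h, whose enzyme makes hydroxylated myelin lipids, had a log2 difference of -0.88 (limma adjusted p = 0.0565), Serpinb1a -1.22 (0.0565), Itgb4 -0.94 (0.0610), the cytokine gene Il33 -1.23 (0.0952), the small nucleolar RNA Snora47 -0.71 (0.0949) and the phosphate transporter gene Slc34a3 -1.97 (0.0981), or -1.19 with normexp, where it was called (0.0249).

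Of the genes chosen before the data were examined because they bear on the disease or mark a cell type, none was called. The log2 differences were -0.11 ± 0.08 (SE) for Cnp and -0.36 ± 0.11 for Mbp, both genes of myelin. They were 0.59 ± 0.11 for Gfap of astrocytes and 0.59 ± 0.10 for Aif1 of microglia. Cst3 had a difference of -0.14 ± 0.14, Tubb3 of neurons 0.06 ± 0.16, Pcp2 of Purkinje cells -0.15 ± 0.10 and Gabra6 of cerebellar granule cells -0.27 ± 0.18. The limma adjusted p of these 8 genes lay between 0.255 for Aif1 and 0.916 for Tubb3.

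With slide as a block, which compares the 2 wild-type and 3 transgenic arrays of slide 2, 7 genes passed, all of them among the 11. Nmu, Kdr, Rasal3 and Gm4524 then missed the threshold with an adjusted p of 0.0818 each, at log2 differences of 5.94, 3.33, 1.23 and -2.37. With the first digit of the title number as a block Nmu, Kdr and Rasal3 missed it (limma adjusted p = 0.0798, 0.0560 and 0.0744), and with no filter on dim probes Nmu, Kdr and Ccl6 did (0.0643 each), as did Rasal3 (0.0925). With 1 sample left out, limma called 0 genes without transgenic replicate 2 (1193 at an unadjusted p under 0.05), 1 without transgenic replicate 1 or wild-type replicate 3, 4 without transgenic replicate 3 or wild-type replicate 2 and 7 without wild-type replicate 1.

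Microglial genes were higher as a group. Of 24 measured genes of the disease-associated microglial state, 21 were higher in the transgenic samples, with a mean log2 difference of 1.12 and a median of 0.28. Over all genes 4 of them passed, Itgax, Ccl3, Clec7a and Ccl6, and 11 passed when adjusted over the list alone, among them Cd68. The other 13 lay between -0.30 for Fth1 and 0.30 for Ctsz, named after their values were seen as the ends of that range, so 11 genes carried the mean. It was 0.59 with normexp and 0.58 with probes well above background on all arrays. Of 22 homeostatic microglial genes, 19 were higher, with a mean of 0.42 and a median of 0.34. None passed over all genes and 11 passed when adjusted over the list alone, all higher, including Trem2 (log2 difference 0.75 ± 0.08), C1qc (0.90 ± 0.11), Ly86 (0.69 ± 0.09) and C1qb (0.80 ± 0.11). Homeostatic is the name of the list as fixed beforehand. Whether its members are particular to that state was not tested. In camera with a preset correlation of 0.01 the Benjamini-Hochberg adjusted p over 31 lists was 1.18e-18 for the disease-associated and 4.64e-12 for the homeostatic genes. Both calls were lost at adjusted p = 0.112 with an estimated correlation. Camera with the preset correlation also called 4 to 11 lists when the arrays were split 3 against 3 in other ways. Its small p-values here and below are therefore not to be taken at face value.

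Interferon-stimulated genes were raised as a group, with 24 of 26 measured members higher and a mean log2 difference of 0.57 (0.37 with normexp). None passed over all genes and 15 passed when adjusted over the list alone, all higher, led by Oas1a, Gbp3 (0.65 ± 0.09), Oas2 (0.70 ± 0.10) and Usp18 (1.22 ± 0.18). Reactive astrocyte genes had a mean of 0.42 (0.28 with normexp) over 22 members, of which none passed over all genes and 6 passed when adjusted over the list alone. Among these were Cd14 (0.92 ± 0.12), the chemokine gene Cxcl10 (2.38 ± 0.43), Gfap and Lcn2 (0.79 ± 0.17), while Vim, an intermediate filament gene of the same list named after its values were seen, had 0.07 ± 0.10. Cd14 and Cxcl10 are also made by microglia. Antigen presentation and complement genes had a mean of 0.39 over 22 members, with 0 calls over all genes and 7 when adjusted over the list alone. The 3 complement genes C1qa, C1qb and C1qc belong to this list and to the homeostatic microglial list, and Nlrc5 (1.08 ± 0.20) was among the other 4. The camera adjusted p was 1.18e-18 for the interferon, 3.14e-08 for the reactive astrocyte and 1.82e-09 for the antigen presentation list. With an estimated correlation the adjusted p = 0.112 for the first 2 and 0.260 for the last.

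**Figure D2:**
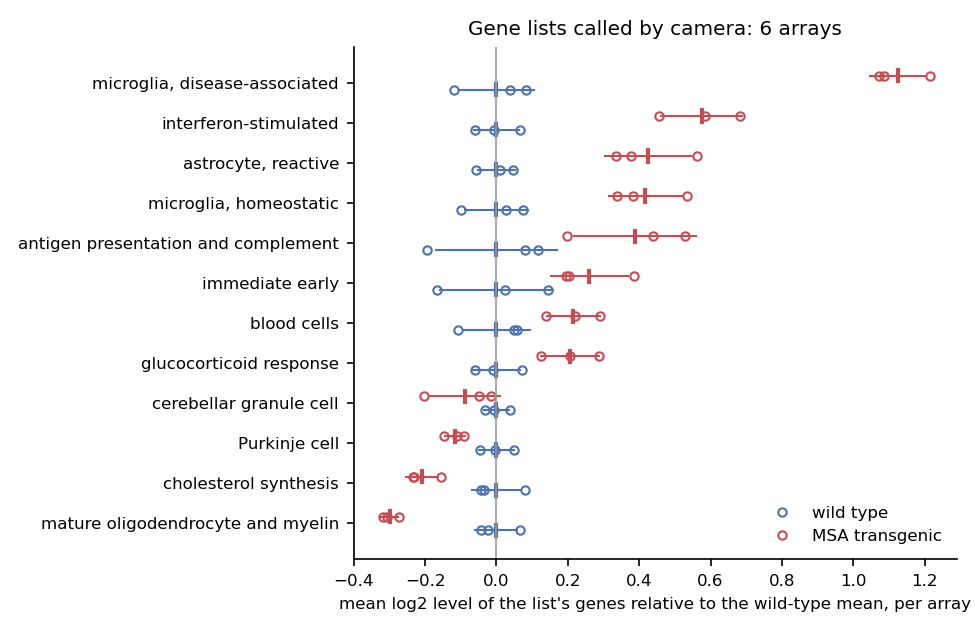
Mean log2 level of the genes of each list on each array, relative to each gene's wild-type mean (horizontal axis), for the 12 lists called by camera with the preset correlation. Open circles are arrays, thick bars the means and thin bars the SD of 3 wild-type (blue) and 3 MSA transgenic (red) arrays, with the disease-associated microglial genes at a transgenic mean of 1.12 and the myelin genes at -0.30.

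Genes of mature oligodendrocytes and myelin were lower as a group, with 24 of 28 measured members below the wild-type level and a mean log2 difference of -0.30. Klk6 passed over all genes, and Klk6, Fa2h and Mog (-0.42 ± 0.09) passed when adjusted over the list alone. Of 23 cholesterol synthesis genes, 21 were lower, with a mean of -0.21. None passed over all genes and 4 passed when adjusted over the list alone, among them Idi1 (-0.46 ± 0.09), Hmgcs1 (-0.45 ± 0.08) and Msmo1 (-0.45 ± 0.11). The camera adjusted p was 4.65e-10 for the myelin and 1.15e-08 for the cholesterol list, and adjusted p = 0.112 and 0.147 with an estimated correlation. Genes of oligodendrocyte precursors and premyelinating cells had a mean of 0.10 (camera adjusted p = 0.157). Their members with the smallest p were Bcas1 (0.52 ± 0.14), Tcf7l2 (0.59 ± 0.17) and Olig2 (0.54 ± 0.18), none of which passed over all genes or adjusted over the list alone.

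Neuronal genes differed less. Purkinje cell genes had a mean log2 difference of -0.12 over 22 members (camera adjusted p = 0.000704, and adjusted p = 0.112 with an estimated correlation), and cerebellar granule cell genes -0.09 over 22 (0.0110, and adjusted p = 0.481 with an estimated correlation). Without transgenic replicate 3 the granule cell mean was -0.032 (camera adjusted p = 0.189). In both lists 0 members passed over all genes and 0 adjusted over the list alone. Casq2 and Calb1 of Purkinje cells differed by -0.22 ± 0.09 and -0.15 ± 0.08, and Zic4, Cbln1 and Zic2 of granule cells by -0.25 ± 0.11, -0.23 ± 0.10 and, in the other direction, 0.51 ± 0.23. Immediate early genes had a mean of 0.26 (0.14 with normexp) over 20 members (camera adjusted p = 8.40e-05, and adjusted p = 0.179 with an estimated correlation), with 0 calls over all genes and 2, Egr2 (0.33 with normexp) and Atf3 (0.75 ± 0.09), adjusted over the list alone. Glucocorticoid response genes had 0.21 over 16 (0.00147, and adjusted p = 0.187 with an estimated correlation), with Cdkn1a at 0.55 ± 0.16 and Fkbp5 at 0.58 ± 0.18. Blood cell genes had 0.22 (0.14 with normexp, 0.35 with no filter) over 15 (0.00715, and adjusted p = 0.169 with an estimated correlation), with Mrc1 and Cd163, which brain macrophages also express, at 0.37 ± 0.09 and 0.54 ± 0.17. In these last 2 lists no member passed over all genes or adjusted over the list alone.

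Within slide 2 the mean log2 differences were 1.06 for disease-associated and 0.37 for homeostatic microglial genes, 0.61 for interferon-stimulated, 0.45 for reactive astrocyte and 0.45 for antigen presentation genes, -0.32 for myelin and -0.17 for cholesterol genes. They were -0.14 for Purkinje and -0.07 for granule cell genes, 0.33 for immediate early, 0.20 for glucocorticoid and 0.24 for blood cell genes. Of these 12 lists, the granule cell list lost its camera call there (adjusted p = 0.0677). No list passed with an estimated correlation, where 8 of the 31 had an unadjusted p under 0.05. In fry, which asks whether a list's genes move one way on balance, 7 of the 12 passed, namely both microglial lists, the interferon, reactive astrocyte, myelin, cholesterol and Purkinje lists.

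The remaining 19 lists were not called by camera. The mean log2 differences of lists for other tissues and cells that the dissection could hold were 0.12 for forebrain neurons, 0.05 for hypothalamus and pituitary, -0.06 for choroid plexus and ependyma, -0.06 for endothelium and pericytes and 0.12 for meninges and fibroblasts. They were -0.09 for brainstem neurons, -0.05 for astrocytes and Bergmann glia, -0.05 for synaptic vesicle genes and -0.01 for genes linked to parkinsonism. Among pathways the mean was -0.01 for the unfolded protein response, -0.02 for heat shock, 0.04 for autophagy and lysosome, -0.04 for oxidative phosphorylation, 0.13 for targets of p53 and apoptosis, 0.11 for cell proliferation and 0.06 for circadian clock output. Genes known to vary between inbred strains had a mean of 0.14 and a median of -0.01. Of the sex chromosome genes, the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y were well above background on all 6 arrays, with a mean difference of -0.09, and Xist was not well above background on any. Within slide 2 camera called 4 of the 19, the oligodendrocyte precursor (0.12), meninges (0.12), oxidative phosphorylation (-0.06) and proliferation (0.14) lists. Over all 6 arrays these had adjusted p = 0.630, 0.616, 0.448 and 0.448 with an estimated correlation, which was not run within slide 2.

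Because the strain background is mixed, the positions of the changed genes were examined. Of the 200 genes with the smallest p, 23 lay on chromosome 11, where 14.7 were expected, and 4 on chromosome 9, where 10.4 were expected. By Fisher's exact test (2-sided) 0 of 21 chromosomes passed after Benjamini-Hochberg adjustment (lowest adjusted p = 0.385), and these 2 had an unadjusted p under 0.05. On a smaller scale, Kdr and Nmu lie 441 kb apart on chromosome 5 (mm9, Kdr probe at 76329309 to 76329368 and Nmu probe at 76769788 to 76769847). Between them, CB056291, a transcript named only by its accession, and Tmem165, which encodes a Golgi membrane protein, had log2 differences of 1.07 ± 0.10 and 0.85 ± 0.10 (limma adjusted p = 0.0567 and 0.0981). The other 3 tested genes of this stretch, Srd5a3, Clock and Gm7467, had 0.26 ± 0.10, 0.05 ± 0.08 and 0.06 ± 0.10. Just beyond Nmu, 4930432L08Rik was well above background on all 3 transgenic arrays and on 0 of the 3 wild-type arrays, and was at least 1.36-fold higher (limma adjusted p = 0.812), a bound set against the dimmest signals well above background. Kit, the nearest tested gene on the other side, had -0.12 ± 0.17, and Exoc1 0.03 ± 0.07. This stretch and the genes named in and beside it, other than Kdr and Nmu, were singled out after their values were seen. The 2 other Kdr probes were not well above background on any array.

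**Figure D3:**
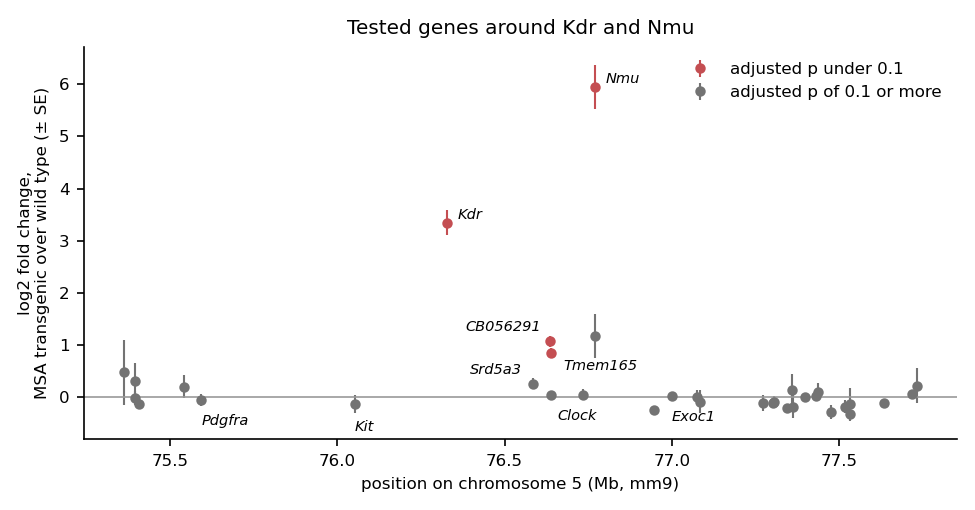
Log2 fold change of MSA transgenic over wild type (vertical axis, bars are SE, n = 3 per genotype) of the tested genes around Kdr and Nmu by probe position on chromosome 5 (horizontal axis, Mb, mm9), in red where the limma adjusted p was under 0.1. Nmu at 5.94 and Kdr at 3.35 stand above CB056291 at 1.07 and Tmem165 at 0.85, with Clock at 0.05 beside them.

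Prnp is read by 2 tested probes that disagreed. The probe whose rise is given above lies at 131763817 to 131763876 on chromosome 2 (mm9) and is annotated to 1 Prnp transcript. A second probe at 131744903 to 131744962, annotated to another Prnp transcript and well above background on all 6 arrays, had a log2 level of 0.69 ± 0.04 (SD) in wild-type and 0.34 ± 0.12 in transgenic samples. With the mean of both probes the log2 difference of Prnp was 1.11. The other 10 called genes each had 1 tested probe.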

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

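All alternatives were fixed before the data were examined. The number of called genes was 11, with 9 higher and 2 lower. It was 29 (19 higher, 10 lower) with normexp, 27 (20 and 7) with an intensity trend in the variance model, 95 (67 and 28) with array weights, 24 (19 and 5) with the mean of a gene's probes, and 23 (17 and 6) with probes well above background on all arrays, where fewer genes were tested. It was 6 (5 and 1) with no filter, where more genes were tested, and 7 (6 and 1) with slide as a block. Each probe by itself gave 11 (10 and 1). Quantile normalization, the authors' value table and the block by the title number's first digit each gave 11, of which 8 were among the main 11 genes, and median scaling gave 16. The block by first digit ended the calls of Nmu, Kdr and Rasal3, and quantile normalization and the authors' table those of Itgax and Rasal3 among the named genes. No filter ended those of Nmu, Kdr, Ccl6 and Rasal3, and Rasal3 also missed the threshold with median scaling and with the intensity trend. At an adjusted p under 0.1 there were 38 (27 and 11) and at an unadjusted p under 0.05 1462 (786 and 676), where 1246.6 are expected by chance. Leaving out 1 sample gave 0 to 7 calls (0 to 6 higher, 0 to 1 lower), with fewer samples in the fit. None was called by limma without transgenic replicate 2, where 1193 had an unadjusted p under 0.05. The 10 called genes with names kept their direction under every alternative run for them. Each probe by itself was not among these, and there the second tested Prnp probe had a log2 difference of -0.35. With normexp the log2 differences were 4.14 for Nmu, 2.31 for Clec7a, 1.42 for Itgax, 1.31 for Ccl3 and 0.21 for Rasal3, and with the mean of its probes 1.11 for Prnp. Of the genes not called, normexp gave 0.38 for Gpr65, 0.33 for Egr2 and 0.57 for Slc11a1, still not called, and -1.19 for Slc34a3, called there. Over the alternatives the limma adjusted p ranged from 0.00206 to 0.265 for Nmu, 0.00344 to 0.190 for Kdr and 0.0119 to 0.543 for Rasal3, 0.00152 to 0.195 for Itgax and 0.00227 to 0.205 for Ccl6, and the camera adjusted p of the granule cell list from 0.00137 to 0.375.

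The number of called lists was 11 to 15 under every alternative but the set tests, with 0 under an estimated correlation and 7 under fry. The 12 called lists kept their direction. With normexp, whose offset by itself shrinks the differences of dim genes, the means fell to 0.59 for disease-associated microglial, 0.37 for interferon, 0.28 for reactive astrocyte, 0.14 for immediate early and 0.14 for blood genes, all still called. The disease-associated mean was 0.58 with probes well above background on all arrays, and the blood mean 0.35 with no filter. Under an estimated correlation, which allows for members moving together, all missed the threshold at unchanged mean log2 differences of 1.12, 0.57, 0.42 (reactive astrocyte), 0.42 (homeostatic), 0.39, 0.26, 0.22, 0.21, -0.089, -0.12, -0.21 and -0.30. Under fry the antigen presentation (0.39), immediate early (0.26), blood (0.22), glucocorticoid (0.21) and granule cell (-0.089) lists missed it. With normexp the Purkinje (-0.11) and granule cell (-0.070) lists missed it, and the granule cell list did so also with no filter (-0.089), with slide as a block (-0.070) and without wild-type replicate 1 or transgenic replicate 3, in a range of -0.13 to -0.032 on leaving out 1 sample. The blood list ranged from 0.16 to 0.25 on leaving out 1 sample and missed it without wild-type replicate 2 or transgenic replicate 2. Among lists and genes that were not called, the sign turned with normexp for forebrain (-0.12), hypothalamus (-0.071), parkinsonism-linked (0.0015), unfolded protein (0.0057), heat shock (0.0038) and proliferation (-0.063) genes. It turned with probes well above background on all arrays for brainstem (0.00090) and forebrain (-0.13) genes, with no filter for hypothalamus (-0.068), with slide as a block for heat shock (0.034), with median scaling for autophagy (-0.0038), and for the unfolded protein list with quantile normalization (0.0018) and the authors' table (0.0017). Cnp had 0.027 with the mean of its probes. Leaving out 1 sample gave -0.22 to 0.11 for brainstem, -0.047 to 0.13 for hypothalamus, -0.18 to 0.035 for choroid plexus, -0.031 to 0.00017 for parkinsonism-linked, -0.078 to 0.057 for unfolded protein, -0.078 to 0.034 for heat shock and -0.016 to 0.090 for autophagy genes, and -0.066 to 0.16 for Tubb3. Where no construction is named, the cause was not tested. The mean share of probes well above background was 70.6%, and 84.6% were positive and significant. The chromosome test called 0 chromosomes by Fisher's exact test in all 12 alternatives run.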

Other observations

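The tests of the 3 patterns below were chosen after the results were seen, while the counts over other splits of the samples were planned. Between a limma adjusted p of 0.05 and 0.1 lay 27 genes, 18 higher and 9 lower in transgenic samples. The 3 against 3 design makes 10 splits, too few for a share under 0.05. The real split, 1 of the 10, called 11 genes and the highest other 0. For gene lists it called 12, 1 of 10 splits reaching that number, and the highest other called 11, with wild-type replicates 2 and 3 and transgenic replicate 1 on one side. Every other split called at least 4 lists, so a camera call with the preset correlation does not by itself set the genotypes apart from other groupings. Each side of such a split holds unequal numbers of the genotypes, so part of their difference remains in it. All splits used the genes that passed the filter by the real genotypes.

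Microglial, interferon and reactive astrocyte lists were higher and the myelin list lower. The array on its own slide did not account for this, since with slide as a block each of the 5 lists kept at least 88.1% of its mean change and its camera call. Equal log2 changes of all homeostatic microglial genes are argued against, since 11 of 22 members lay over 2 SEs from their weighted mean (2.55 expected by chance). The number was 15 with normexp and 14 with slide as a block, and this count was chosen after the members' values had been looked at. P2ry12 had 0.05 ± 0.15 and Tyrobp 0.93 ± 0.13, both named after their values were seen. The members were not tested for belonging to 1 microglial state, so a list that mixes states could give such a spread too. More microglia alone stays open only if the genes that changed less are also expressed by other cells, which was not tested. Clec7a rose by 3.32 ± 0.19 (2.31 with normexp), where Trem2 had 0.75 ± 0.08 and C1qc 0.90 ± 0.11. A change in number alone would need such expression by other cells for Trem2 and C1qc. Clec7a is among the genes that rose most, and the medians, 0.28 for disease-associated and 0.34 for homeostatic genes, show no such gap. These values therefore do not decide it. Blood left in the tissue stays open, since the blood cell mean of 0.22 was far below 1.12 and met its bound, while the medians were 0.29 and 0.28 and Hba-a1, Hba-a2 and S100a8, the first 2 named after their values were seen, had 0.30, 0.29 and 0.98. More microglia together with a change in their genes stays open and was not tested, and calls of these lists were lost with an estimated correlation.

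Prnp was higher at the probe nearer its 3′ end only. A rise of all Prnp transcripts alike is argued against by the other probe, at -0.35 (SD 0.09) where the first had 2.56. A segment of another strain reaching into the 5 Mb on either side stays open, since 4.58% of tested genes there had an unadjusted p under 0.05 against 5.86% of all genes (6 of 131, Fisher's exact test, 2-sided, p = 0.708), a share that met the bound set against it but differed from all genes by less than counting error. A transgene transcript that ends with the end of Prnp, as transgenes built on Prnp expression cassettes give, may account for the difference of 2.91 between the probes. A native transcript ending there gives the same value and the labels do not name the transgene, so these cannot be told apart.

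On chromosome 5, Kdr, CB056291, Tmem165 and Nmu were higher within 441 kb. The probes of CB056291 and Tmem165 start at 76634717 and 76637909. Whether they read separate transcripts was not tested, so these may not be 4 separate genes. More endothelial cells are argued against by a mean of -0.057 for 17 endothelial and pericyte genes, where Kdr had 3.35. The SE of that mean, 0.031, is over these genes and does not measure the spread between samples. A strain segment reaching into the 5 Mb on either side stays open, with 7.46% of tested genes there at an unadjusted p under 0.05 against 5.86% of all genes (5 of 67, Fisher's exact test, 2-sided, p = 0.596). An effect of the transgene's insertion at this place may be a candidate explanation, but the bound set against it was met, since another stretch of that length, on chromosome 11, held as many genes with an adjusted p under 0.1 and a log2 difference of at least 0.8, limits set after the stretch was seen (4, namely Ccl9, Ccl6, Ccl3 and Ccl4, with Ccl9 and Ccl4 named after their values were seen). That bound was judged wrong only after this was seen, because neighbouring chemokine genes of 1 family changing together says nothing of an insertion elsewhere, so the insertion is neither excluded nor shown.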
